A study of Mus musculus with 3 samples.

How the data were processed

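Spinal cords of mouse embryos at embryonic day 13.5 were stored in a preservative, RNA was extracted with Trizol, and libraries were made from 1 µg of total RNA with the VAHTS mRNA-seq V2 kit (Vazyme), per the labels' protocols. The submitters' processing notes name CASAVA, Bowtie2 2.3.2 and the genome GRCm38.p6, without roles. The quantification tool, the annotation release and whether strand was used are not given in the sources used here, so overlapping genes and antisense partners cannot be told apart. Each of the 3 libraries is 1 genotype, and the labels do not say how many embryos each holds. The names of the WT and dE3 libraries carry the tag L2 and that of the cKO library L3, so that this tag cannot be separated from the cKO genotype.

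The authors deposited tables of estimated counts per gene and per transcript, and TPM and FPKM values for the same features, named per the file headers. The deposited estimated counts were whole numbers. No transcript with a count of 0 had a TPM above 0, and counts of 1 stood beside FPKM values worth far less than 1 read, so fractional estimates appear to have been rounded up per transcript. Gene counts equalled the sum of their transcripts' counts for every gene. The TPM values of the authors, which divide by transcript length, served as an alternative only, and the deposited FPKM values were used only to examine the units. The deposited tables held 51826 genes and 128622 transcripts. Of the gene IDs, 51633 matched a table of reference names, and 98.5% matched GENCODE vM21, which gave coordinates on GRCm38.

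Library sizes were 32167470 (WT), 34790053 (dE3) and 33048837 (cKO) counts, scaled by TMM (edgeR 4.0.16 in R 4.3.3) with factors of 0.993, 1.01 and 0.999. CPM values are counts scaled to these sizes. Genes with a count of at least 20 in at least 1 library were measured (18074 genes). The median log2 ratio over all measured genes was 0.00 (dE3 against WT), 0.00 (cKO against WT) and 0.02 (dE3 against cKO). Mitochondrial genes took 2.97%, 2.52% and 2.24% of counts.

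Each ratio of scaled counts had an exact conditional binomial (Clopper-Pearson) interval at 95%. Reads without molecular identifiers are not independent molecules, and the counts are estimates, so intervals and floors cover counting error only. A gene was called higher or lower when the ratio was at least 2 and the interval excluded 1. No p-value was computed, since 1 library per group gives no spread between replicates. A gene at 0 in a library was set against a floor of 3 counts in that library and its ratio given as a bound, which also entered list medians. The bound takes the count of the other library as observed. The floor corresponds to 0.0939 CPM in WT, 0.0856 in dE3 and 0.0908 in cKO.

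Gene lists (43, with 623 distinct symbols, of which 621 matched the tables) covered the Wnt pathway, other signals, progenitor and neuron classes, glia, cell states, axial level, sex, housekeeping genes and markers of tissues that a dissection could hold. For each list with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size matched in 20 bins of mean expression. Lists in the outer 2.5% on either side were called standing apart, as a description of these libraries. Of 43 lists, 26 stood apart in dE3 against WT (14 high and 12 low), 26 in cKO against WT (20 and 6) and 29 in dE3 against cKO (14 and 15), where chance gives 2.15. Genes share regulation, so lists vary more than random ones.

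The genes named were set by a rule. For each mutant against WT it took the 12 genes higher and the 12 lower whose interval bound nearest to 1 lay farthest from 1 (5 and 5 for dE3 against cKO). It left out Gm-number, Rik, clone-named, pseudogene, mt-, Rpl, Rps and unnamed genes. It added Ctnnb1, Neurog2, Gfap, the Wnt target list and up to 4 members of each other list. Some genes that the rule selects are not reported here. Further members of the lists that are named as examples, and mt-Atp6 and Gm10925, were chosen after their values were seen.

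Sequence sharing was measured as the percent of a gene's 50-base words, sampled at 1 in 16, that occur on either strand in another gene's GENCODE vM21 transcripts. For genes with several transcripts the ratio was also computed without the transcript whose counts differed most. The excess ratio of a gene was the cKO value minus WT divided by the dE3 value minus WT, in CPM. For genes in the same or opposite direction, unchanged libraries, WT included, were simulated 100 times from the pooled counts. The assumed biological coefficients of variation were 0, 0.1 and 0.2.

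The calls were tested on simulated data for dE3 against WT with 17440 genes, of which 200 had known folds. The rule recovered 50 of 50 genes 4-fold lower, 50 of 50 genes 3-fold lower, 49 of 50 genes 3-fold higher and 50 of 50 genes 4-fold higher. It called 62 unchanged genes (0.36%), and the intervals covered the true ratio for 95.4% of genes. The simulated counts held counting error alone (Poisson draws), so both values follow from that design. They leave out biological variation and are not error rates for these libraries. Of 40 lists of 20 genes each shifted by 0.5, 40 stood apart, and 3 of 40 unshifted ones did.

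Alternatives covered total-count, median-of-ratios (DESeq2 1.42.0) and upper-quartile scaling, other count minimums, fold thresholds of 1.5 and 4, a pseudocount of 5 scaled counts, and the TPM values with a pseudocount of 0.5. They also covered sums of transcript counts, removal of haemoglobin, mitochondrial and the 50 most abundant genes, the mean in place of the median, and 5 bins for matching. A last alternative left out genes sharing 20% or more of their words. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.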

Results

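RNA of spinal cord from mouse embryos (C57BL/6) at embryonic day 13.5 was sequenced from 3 genotypes, with 1 library per genotype. The genotypes were wild type (WT), a Nestin-Cre deletion of Ctnnb1 exon 3 that the labels describe as gain of function (dE3), and a Nestin-Cre deletion of Ctnnb1 exons 2 to 6 that they describe as loss of function (cKO). Ctnnb1 encodes β-catenin, which carries canonical Wnt signals to TCF/LEF transcription factors and binds cadherins at cell junctions. Exon 3 encodes the residues whose phosphorylation marks β-catenin for degradation, and Nestin-Cre recombines in neural progenitors. The comparisons ask how a stabilised and a missing β-catenin alter gene expression in the embryonic cord, at the stage when neuron production gives way to the generation of glia. The libraries held 32167470 (WT), 34790053 (dE3) and 33048837 (cKO) estimated counts, and 18074 genes were measured. With 1 library per genotype no difference has a replicate check, and every interval given covers counting error only. The values compare these libraries, not the genotypes at large.

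The targeted gene was present in all 3 libraries. Ctnnb1 (ENSMUSG00000006932, chromosome 9, 120929216 to 120960507, plus strand, GRCm38) stood at 544 CPM (counts scaled to library size) in WT, 461 in dE3 and 422 in cKO. The ratio to WT was 0.847 (95% counting interval 0.829 to 0.866) in dE3 and 0.776 (0.758 to 0.793) in cKO. Exon 3, a coding exon at 120950522 to 120950749, holds 228 of the 3623 bases of the spliced transcript (6.29%). Exons 2 to 6, at 120950173 to 120951787 with their introns, hold 984 bases (27.2%). The gene total therefore also counts exons outside the deleted parts and cells without recombination, so it checks the labels only in part. By the TPM values of the authors the log2 ratio to WT was -0.0262 in dE3 and -0.52 in cKO, against -0.24 and -0.37 from counts. Without the transcript whose counts differed most, the log2 ratio was -1.27 in dE3 and 0.18 in cKO.

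The dE3 library held far more RNA of Wnt feedback and target genes than the WT library. Wif1, a secreted Wnt antagonist, was 153-fold higher (118 to 201), at 277 CPM against 1.82, and Nkd1, a feedback inhibitor, was 16.4-fold higher (15.6 to 17.3), at 804 CPM against 48.9. Neurog2, the proneural transcription factor, was 9.99-fold higher (9.26 to 10.8), at 232 CPM against 23.2. In the other direction, Olig2, which specifies motor neuron and oligodendrocyte progenitors, had 532 counts in WT and 0 in dE3, at least 195-fold lower. Several astrocyte lineage genes were also lower, with the GABA transporter Slc6a11 7.97-fold lower (7.37 to 8.64) in dE3. The same library held more RNA of skeletal muscle and cartilage genes, with list medians of 4.05 and 5.04 on the log2 scale.

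Among 21 measured Wnt/β-catenin feedback and target genes, 14 were at least 2-fold higher in dE3 than in WT, 0 were lower and 7 were neither. Their median log2 ratio was 1.5, at percentile 100 of 10000 random lists matched on expression. Axin2, the scaffold of the β-catenin destruction complex and a common Wnt readout, was 6.67-fold higher (6.30 to 7.07), and the transcription factor Lef1 was 14.8-fold higher (12.6 to 17.5). Sp5, a direct target, was 38.2-fold higher (28.9 to 51.7), and Rnf43, a ubiquitin ligase that removes Wnt receptors, was 41.9-fold higher (25.6 to 73.7). Notum, a secreted enzyme that inactivates Wnt proteins, was 72.3-fold higher (55.8 to 95.4), but shared 31.2% of its 50-base words with the antisense gene Notumos. Tnfrsf19 and Apcdd1 were 9.89-fold (9.29 to 10.5) and 4.22-fold higher (4.09 to 4.37). For the 14 genes higher in dE3, the median excess over WT in the cKO library was 0.0190 of that in the dE3 library, against 0.227 for the muscle and cartilage genes.

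**Figure D1:**
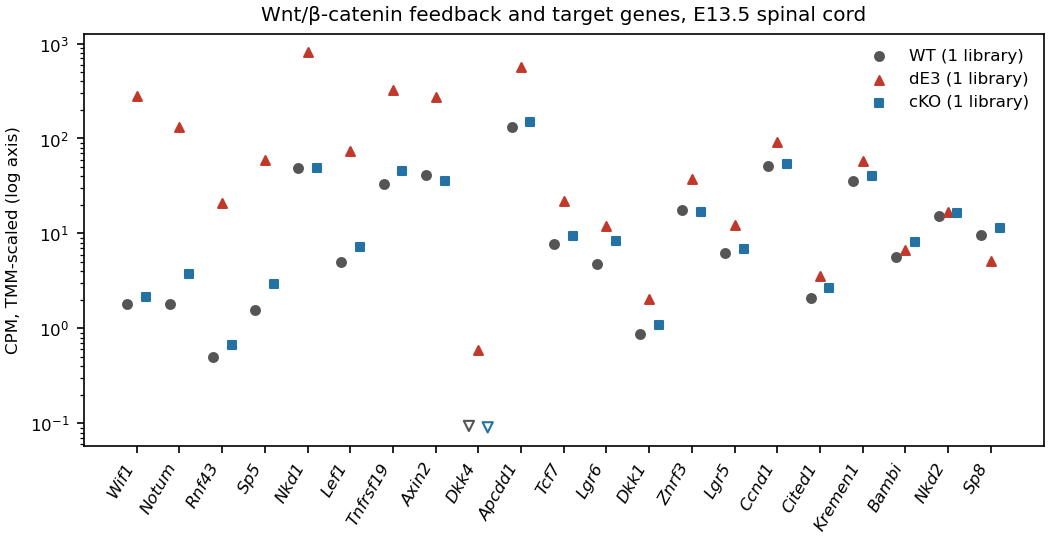
Scaled counts (CPM, log axis) of the 21 measured Wnt/β-catenin feedback and target genes in the WT, dE3 and cKO libraries, 1 point per library with no replicate error; open triangles mark a count of 0, drawn at the level of 3 counts. 14 of the 21 genes lay at least 2-fold higher in dE3 than in WT, and 1 of them (Notum) in cKO than in WT, where its log2 ratio was -0.17 without its most different transcript.

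Other parts of the Wnt pathway differed less evenly between dE3 and WT. Wnt receptors and co-receptors had a median of 0.54 (percentile 100), with 3 of 16 members higher and 0 lower. Among the genes higher, the receptor Fzd10 was 7.64-fold higher (7.22 to 8.08). The others were Ror1 and Ror2, which had log2 ratios of 0.57 and 1.14 in cKO as well, and Ror2 had a log2 ratio of -5.56 in dE3 without its most different transcript. The excess over WT in cKO, relative to that in dE3, had a median of 0.381 over these 3 receptors (-0.0288, for Fzd10, to 0.438) and of 0.247 over the 6 Wnt ligands higher in dE3 (-0.154 to 1.82). The central 90% of the muscle and cartilage genes was 0.0774 to 0.416. The 17 measured Wnt ligands went both ways, with 6 higher, 3 lower and a median of 0.01 (percentile 39.5). Wnt10a was 146-fold higher (40.1 to 1210) with 2 counts in WT and 320 in dE3, while Wnt7b was 3.25-fold lower (3.0 to 3.51) and Wnt1, a roof plate ligand, 4.16-fold lower (2.91 to 6.09). Secreted Wnt modulators (median -0.05, percentile 32.7) had 1 of 12 members higher, namely Dkk2, at 3.12-fold (2.42 to 4.07). The list of β-catenin complex and TCF cofactor genes had a median of 0.05 (percentile 90.3) and 0 of 16 members past 2-fold. Cadherin-catenin adhesion genes had a median of -0.16 (percentile 2.35), with 1 of 18 lower (Cdh20, 2.12-fold, 1.75 to 2.56).

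Several dorsal patterning genes were higher in dE3, and a few intermediate and ventral ones were lower. Of 17 roof plate and dorsal progenitor genes, 8 were higher and 3 lower, with a median of 0.89 (percentile 100). Prdm13, a regulator of dorsal inhibitory neurons, was 5.78-fold higher (5.11 to 6.56), Zic5 was 4.42-fold higher (4.06 to 4.83) and Msx2, a target of BMP signals, was 4.10-fold higher (3.13 to 5.44). Gsx2, which marks dorsal interneuron progenitors, was 10.1-fold lower (4.34 to 28.6). Of 15 ventral and intermediate progenitor genes, 3 were lower and 0 higher, with a median of -0.24 (percentile 1.47). These 3 were Olig2, Dbx1 (24.9-fold lower, 12.8 to 55.2) and Dbx2 (21.0-fold lower, 10.4 to 49.5), the Dbx genes marking progenitors at the middle of the dorsoventral axis.

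Proneural genes split, while neuronal genes lay slightly lower as a group. Among 20 proneural and neurogenic genes (median 0.20, percentile 99.5), 2 were higher and 2 lower. Neurog2 and Btg2, an antiproliferative gene of neurogenic divisions (2.18-fold, 2.02 to 2.34), were the genes higher. Atoh1, a proneural factor of dorsal progenitors (4.17-fold, 2.04 to 9.38), was among those lower. None of 23 pan-neuronal genes passed 2-fold, and their median was -0.37 (percentile 0). The medians were -0.38 for glutamatergic neuron genes (percentile 0.06, 1 of 13 lower), -0.16 for GABAergic and glycinergic ones (percentile 2.04, 0 of 16 past 2-fold) and -0.45 for motor neuron genes (percentile 0, 1 of 14 lower). Dorsal interneuron transcription factors had a median of -0.22 (percentile 0.33, 2 of 18 lower). Among them Lmx1b, needed for dorsal horn excitatory neurons, was 2.16-fold lower (2.07 to 2.27) and Tlx1 was 11.8-fold lower (4.29 to 45.2). Ventral interneuron transcription factors had a median of -0.29 (percentile 0.63), with 1 of 13 higher and 1 lower.

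Genes of the glial lineages were lower in part. Of 23 astrocyte lineage genes, 9 were lower in dE3, 1 was higher and 13 were neither, with a median of -0.53 (percentile 0). Besides Slc6a11, the adhesion gene Hepacam was 4.83-fold lower (3.97 to 5.92). The fatty acid binding protein gene Fabp7 was 3.05-fold lower (2.95 to 3.15) and the receptor gene Fgfr3 2.75-fold lower (2.53 to 2.98). Fabp7 is also in the neural progenitor and Schwann lists, and Fgfr3 in the FGF list. Gfap, the classical astrocyte filament gene, had 2 counts in WT, 13 in dE3 and 5 in cKO, below the minimum for a call. Of 17 oligodendrocyte lineage genes, 3 were lower and 0 higher, with a median of -0.24 (percentile 0.705). Olig1 (chromosome 16, 91269772 to 91271933) had 1064 counts in WT and 2 in dE3, a 584-fold difference (161 to 4825), and Sox8 was 5.72-fold lower (4.71 to 6.99). Sox10 (18.8 CPM in WT, 17.0 in dE3), which Schwann cells also express, was not past 2-fold. Neural progenitor genes had a median of 0.07 (percentile 91.2), with 5 of 17 lower, among them Sox1 (2.94-fold, 2.54 to 3.43) and Ednrb (3.16-fold, 2.98 to 3.35), and 1 higher, the Notch target Hes5 (2.3-fold, 2.13 to 2.48), which shared 23.5% of its words with another gene and had a log2 ratio of 0.81 without its most different transcript.

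Genes of the cell cycle were higher in dE3. The median of 20 G2 and M phase genes was 0.82 and that of 20 S phase genes 0.58 (both at percentile 100), with 5 of each list past 2-fold and 0 lower. Birc5, a mitotic regulator, had 4.69 CPM in WT and 14.2 in dE3, and the replication gene Mcm3 had 15 and 36.1. Cell cycle exit genes and inhibitors also had a positive median, 0.45 (percentile 100), with 2 of 11 higher, Btg2 and the p21 gene Cdkn1a (3.09-fold, 2.81 to 3.41). Hedgehog pathway genes had a median of 0.41 (percentile 99.9), with 4 of 11 higher, among them Gli1, a target of the pathway (2.38-fold, 2.08 to 2.72). The median excess over WT in cKO, relative to that in dE3, was 0.312 for the G2 and M phase genes past 2-fold (-0.0327 to 0.787), 0.162 for the S phase genes (-0.0777 to 0.456) and 0.148 for the Hedgehog genes (-0.0370 to 0.588). These medians lay inside the central 90% of the muscle and cartilage genes (0.0774 to 0.416, with members from 0 to 0.564) while single members lay on both sides of it, and the median of the dorsal patterning genes (-0.101) lay below it. BMP pathway genes had a median of 0.22 (percentile 98.7), with 2 of 18 higher, Bmp4 (2.74-fold, 1.99 to 3.81) and the antagonist Grem1 (3.25-fold, 2.87 to 3.69). Notch genes (median 0.05, percentile 79.0, 2 of 17 higher) and FGF genes (median -0.05, percentile 27.4, 2 of 14 lower) did not stand apart from random lists.

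Markers of tissues around the cord differed as well. All 14 measured skeletal muscle genes and all 13 cartilage and vertebra genes were higher in dE3 than in WT, both lists at percentile 100. Of these, 0 muscle and 3 cartilage genes reached 10 CPM in WT, and no other list holds any of them. The muscle actin gene Actc1 was 19.6-fold higher (15.4 to 25.3) at 42.9 CPM, and Col2a1, the main cartilage collagen gene, 4.87-fold higher (4.68 to 5.07) at 432 CPM. Epidermis genes had a median of 1.53 (percentile 100, 8 of 10 higher), meninges and mesenchyme genes 0.93 (percentile 100, 6 of 16 higher), and pericyte and smooth muscle genes 0.35 (percentile 99.5, 2 of 10 higher). Dorsal root ganglion genes lay lower, at -0.34 (percentile 0, 0 of 16 past 2-fold). Endothelial (0.15, percentile 90.9), microglia and macrophage (0.13, percentile 76.8), erythroid (-0.07, percentile 35.9) and Schwann and neural crest genes (0.04, percentile 60.7) did not stand apart.

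Across all measured genes, 1178 were at least 2-fold higher and 683 lower in dE3 than in WT, of which 405 and 205 passed 4-fold. The named genes with the clearest excess were Mybpc1, a muscle myosin-binding protein gene (253-fold, 198 to 330, at 499 CPM), then Wif1, Tnni1 (at least 75.4-fold), Pax1, Notum, Scin (at least 54.1-fold), Wnt10a, Notumos, Col9a1, Acan, Matn1 and Edar, the ectodysplasin receptor gene (88.9-fold, 34.4 to 328). The cKO excess was 0.00182 of the dE3 excess for Mybpc1 and 0.0622 for Pax1, a vertebral column regulator. The clearest deficits were Olig1, Olig2, Gstp2, Itgam, Pcdhb21 (28.6-fold, 16.5 to 54.3), Pcdhgb4, Tmem170b, SETD1A, Dbx1, Vcp-rs, Dbx2 and Folh1 (at least 11.0-fold). Of these, SETD1A shared 98.2% of its words with Setd1a, Vcp-rs 79.9% with Vcp, the listed Itgam gene 77.3% with another gene of that symbol, Gstp2 54.0% with Gstp1 and Pcdhgb4 43.5% with Pcdhgb5. Without the transcript that differed most, Pcdhgb4 and Tmem170b had log2 ratios of only -0.59 and -0.81. Among genes lower in dE3, 27.5% shared 20% or more of their words with another gene, against 14.2% of all measured genes. With at least 100 counts required, 636 genes were higher and 246 lower.

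**Figure D2:**
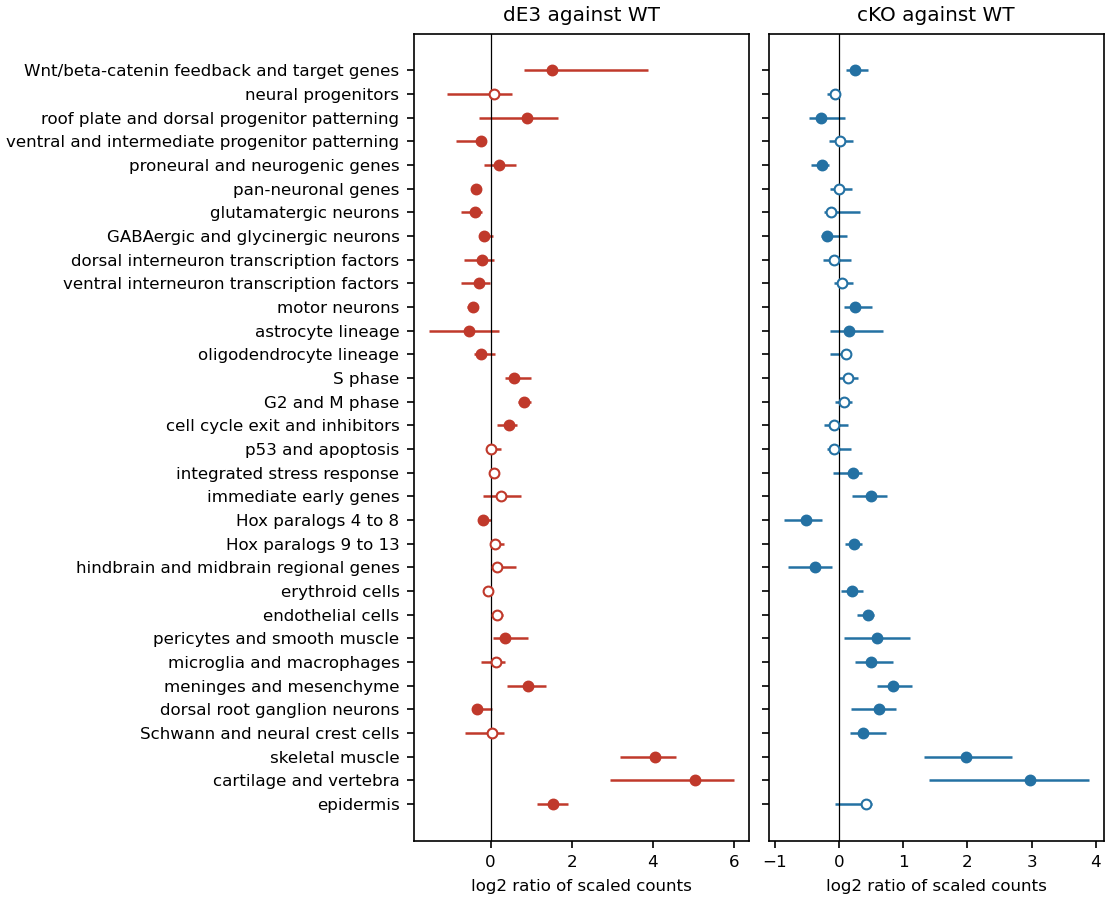
Median log2 ratio (points) and interquartile range over members (lines) of the Wnt target list and of the neural, cell state, axial level and other cell type lists, dE3 and cKO each against WT (1 library each; the horizontal scales differ); filled points lie in the outer 2.5% of random lists on either side. Muscle and cartilage lists lay highest in both, at 4.05 and 5.04 in dE3 and 1.99 and 2.97 in cKO, and the astrocyte list lay at -0.53 in dE3 and 0.15 in cKO.

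Between cKO and WT, Wnt target genes were not lower as a list. Axin2 stood at 35.8 CPM in cKO and 41.3 in WT (1.16-fold lower, 1.07 to 1.25), and Nkd1 at 48.6 and 48.9. Neurog2 was 1.41-fold lower (1.26 to 1.58), at 16.4 CPM against 23.2, below the 2-fold threshold. Olig1 stood at 36.3 CPM against 33.3 and Slc6a11 at 178 against 160. Genes of muscle and cartilage were higher in cKO than in WT, by less than in dE3, and those of mesenchyme by about as much as in dE3. Small positive medians were common in cKO: 20 of 43 lists stood apart on the high side, and the list of housekeeping genes, a control, had a median of 0.17 (percentile 99.7).

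Of the 21 Wnt target genes, 1 was at least 2-fold higher in cKO than in WT (Notum, 2.07-fold, 1.5 to 2.88) and 0 were lower, with a median of 0.25 (percentile 99.9). Without its most different transcript Notum had a log2 ratio of -0.17, so that call rests on 1 transcript. In all, 17 of the 21 lay above 0 and 3 below. Only 8 of the 21 reached 10 CPM in WT, and their log2 ratios ran from -0.21 (Axin2) to 0.45 (Tnfrsf19). Wnt receptors (median 0.24, percentile 99.9) had 1 of 16 members higher, Ror2 (2.20-fold, 1.86 to 2.61), a receptor for Wnt5a that mesenchyme also uses, with a log2 ratio of 0.50 without its most different transcript. Wnt ligands (median 0.37, percentile 99.5) had 3 of 17 higher, among them Wnt6 (2.79-fold, 2.21 to 3.56), and 1 lower. Secreted modulators (0.19, percentile 97.1, 1 of 12 higher) did not stand apart. Neither did the β-catenin complex (0.00, percentile 54.5) and cadherin-catenin lists (0.10, percentile 96.8), with no member past 2-fold. BMP genes had a median of 0.27 (percentile 99.97) with 1 of 18 higher, Bmp4 (2.14-fold, 1.53 to 3.01), and Hedgehog genes 0.22 (percentile 99.3) with none past 2-fold. Notch (0.12, percentile 96.8) and FGF genes (0.14, percentile 93.4) had no member past 2-fold.

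Dorsal patterning and proneural genes lay lower in cKO, by small amounts. Roof plate and dorsal progenitor genes had a median of -0.28 (percentile 0.19), and 1 of 17 was past 2-fold, Msx3 (2.19-fold lower, 1.92 to 2.49), a dorsal homeobox gene whose log2 ratio was -0.57 without its most different transcript. The proneural list had a median of -0.27 (percentile 0.02) with 1 of 20 lower, Atoh1 (3.93-fold, 1.92 to 8.84), and 0 higher. Neural progenitor (-0.06, percentile 15.8) and ventral progenitor genes (0.02, percentile 54.2) had no member past 2-fold. The same was true of pan-neuronal (0.00, percentile 50.3), glutamatergic (-0.13, percentile 7.78), GABAergic and glycinergic (-0.19, percentile 0.44), dorsal interneuron (-0.08, percentile 12.1) and ventral interneuron genes (0.05, percentile 58.8). Motor neuron genes had a median of 0.24 (percentile 99.8) and none of 14 past 2-fold. Among them the neurofilament gene Prph, which is also in the dorsal root ganglion list (median 0.62 in cKO), stood at 276 CPM against 150, with a log2 ratio of 0.27 without its most different transcript.

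Astrocyte lineage genes had a median of 0.15 in cKO (percentile 99.4), no higher than that of the housekeeping genes (0.17), with 4 of 23 higher and 0 lower. The 4 were S100b, Gjb6, Gpr37l1 and Ntsr2, all under 10 CPM, while Fgfr3 stood at 70.1 CPM against 64.5 and Fabp7 at 358 against 446. Oligodendrocyte lineage genes had a median of 0.10 (percentile 80.6) with 1 of 17 lower, the myelin gene Mog (2.06 CPM against 4.82). S phase (0.15, percentile 97.1), G2 and M phase (0.08, percentile 78.8) and cell cycle exit genes (-0.08, percentile 17.0) had no member past 2-fold.

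Markers of rostral axial levels were lower in cKO. The labels do not state which axial range of the cord each library holds, so level and genotype are not separable here. Hox paralogs 4 to 8, which mark cervical and upper thoracic levels, had a median of -0.51 (percentile 0) with 3 of 15 lower, among them Hoxa4 (6.12 CPM against 20.1) and Hoxa5 (68.9 against 140). Hindbrain and midbrain genes had a median of -0.38 (percentile 0.08), with 2 of 10 lower and 1 higher. Hox paralogs 9 to 13, which mark more caudal levels, had a median of 0.24 (percentile 99.9) with none of 14 past 2-fold. In dE3 the medians of these lists were -0.18 (percentile 1.47), 0.15 (percentile 90.4, 2 of 10 higher and 1 lower) and 0.11 (percentile 92.6, 3 of 14 higher).

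Lists of surrounding and blood-borne tissues lay higher in cKO than in WT. Skeletal muscle genes had a median of 1.99 (11 of 14 higher), cartilage genes 2.97 (11 of 13 higher), meninges and mesenchyme genes 0.84 (6 of 16 higher), dorsal root ganglion genes 0.62 (2 of 16 higher), pericyte genes 0.59 (4 of 10 higher) and endothelial genes 0.46 (none of 15 past 2-fold), all at percentile 100. Among them Acan, the main cartilage proteoglycan gene, was 17.8-fold higher (12.5 to 26.1). Microglia and macrophage genes had a median of 0.49 (percentile 99.96), Schwann and neural crest genes 0.37 (percentile 99.95), and erythroid genes 0.20 (percentile 98.4). Epidermis genes (0.42, percentile 97, 1 of 10 higher) did not stand apart.

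Across all measured genes, 629 were at least 2-fold higher and 617 lower in cKO than in WT, of which 168 and 147 passed 4-fold. The named genes with the clearest excess were Mir686, Trpc2, Fam205a2, Tsix, Comp, Matn1, Acan, Col9a1, Vgll2, Arl5b, Tnni1 and Higd1c. Comp, a cartilage matrix gene, was 50.8-fold higher (13.7 to 425) with 2 counts in WT, and Matn1, also of cartilage, was 24.2-fold higher (13.3 to 49.0). Vgll2, a muscle cofactor gene, was at least 13.2-fold higher. Mir686, Trpc2 and Fam205a2 shared nearly all of their words with Psmb5, Xntrpc and Fam205a4, Higd1c shared 61.9% with Methig1 and Tsix 34.8% with Xist, and without its most different transcript Arl5b had a log2 ratio of 0.52. The clearest deficits included Zfhx2os, Cldn34c2, Xntrpc, Fam205a1, Cntf, SETD1A, Adat3, Cd59b, Dnal1 and Tgfa. SETD1A, Cldn34c2, Zfhx2os, Cntf and Xntrpc shared 98.2%, 97.1%, 91.9%, 89.8% and 85.8% of their words with Setd1a, Cldn34c1, Zfhx2, Zfp91 and Trpc2. Adat3 and Fam205a1 shared 67.5% and 67.2% with Scamp4 and Fam205a4, and Dnal1 had a log2 ratio of -0.19 without its most different transcript. Tgfa, an EGF receptor ligand gene (7.0-fold lower, 6.00 to 8.21), shared 1.23%. Of the genes for which the rest could be tested, 18.8% (16 of 85) of those lower and 29.5% (43 of 146) of those higher in cKO stayed past 2-fold without their most different transcript. For dE3 against WT these were 41.4% (58 of 140) and 54.2% (214 of 395). With at least 100 counts required, 257 genes were higher and 144 lower.

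Set against each other without the WT library, dE3 was higher than cKO in many Wnt targets and dorsal factors and lower in many astrocyte lineage genes. Fzd10 was 9.44-fold higher (8.88 to 10) and Neurog2 14.1-fold higher (12.9 to 15.4) in dE3, and Hoxb1, a hindbrain Hox gene that stood at 32.3 CPM in dE3, was 50.8-fold higher (33.1 to 82.4). Wnt targets had a median of 1.23 (percentile 100, 12 of 21 higher and 1 lower), dorsal patterning genes 1.04 (percentile 100, 9 of 17 higher and 4 lower) and proneural genes 0.41 (percentile 99.99, 4 of 20 higher and 1 lower). Astrocyte lineage genes had a median of -1.29 (percentile 0, 13 of 23 lower and 1 higher), with Slc6a11 8.87-fold lower (8.20 to 9.60). Oligodendrocyte lineage genes had a median of -0.28 (percentile 1.21, 3 of 17 lower and 1 higher), and motor neuron genes -0.80 (percentile 0, 4 of 14 lower and 1 higher). Dorsal root ganglion genes (-0.69, percentile 0, 6 of 16 lower) were lower too, while muscle (1.90, percentile 100, 14 of 14 higher) and cartilage genes (1.57, percentile 100, 10 of 13 higher) were higher. In all, 1196 genes were at least 2-fold higher and 792 lower in dE3 than in cKO. The clearest were Mybpc1, Zfhx2os, Wif1, Hoxb1 and Notum among those higher, and Olig1, Olig2, Mir686, Trpc2 and Fam205a2 among those lower. With at least 100 counts required, 555 were higher and 357 lower.

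Genes were compared for the same or opposite direction against the shared WT library. The 2 mutants were both higher than WT for 316 genes and both lower for 154, while 34 genes were higher in dE3 and lower in cKO and 13 lower in dE3 and higher in cKO. Hoxb1 and Msx3 were among the 34, and Col9a1, Acan and Actc1 among the 316. Independent lists of these sizes would share 41.0, 23.3, 40.2 and 23.8 genes. Unchanged libraries were also drawn from the pooled counts, with 1 simulated WT library shared by both comparisons. They gave 7.01, 3.74, 0 and 0 genes with counting error alone. With an assumed biological coefficient of variation of 0.2 they gave 72.6, 40.6, 0.11 and 0.13. Across genes, which are not independent replicates, the log2 ratios had a correlation of 0.387, below the 0.512 and 0.502 of the simulated unchanged libraries, so the correlation alone shows nothing beyond the shared WT library. The covariance was 0.203, against simulated values of 0.0213 and 0.111. The WT library cannot be split, so part of the excess in the same direction may come from the shared control.

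**Figure D3:**
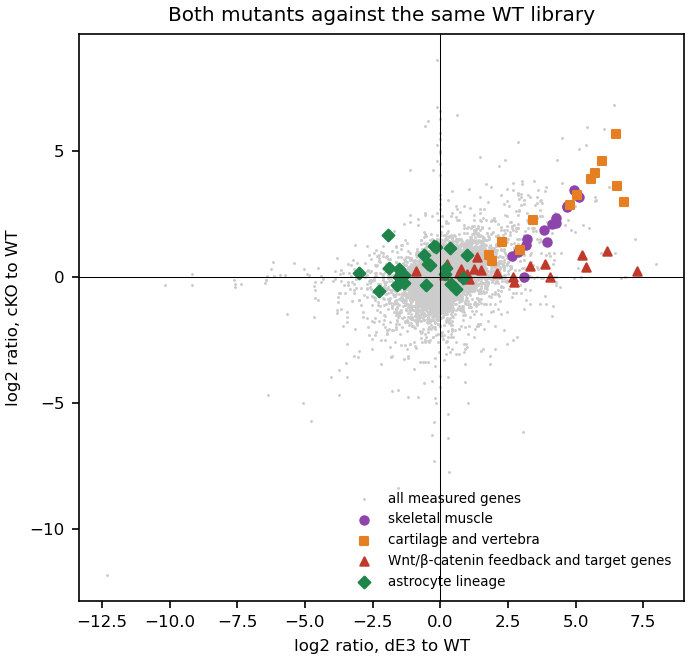
Log2 ratio to the same WT library of each measured gene, dE3 on the horizontal and cKO on the vertical axis, 1 point per gene and 1 library per genotype. Skeletal muscle and cartilage genes lay above 0 in dE3 and mostly in cKO (11 of 14 and 11 of 13 at least 2-fold higher), while Wnt targets lay high in dE3 (median 1.5) and near 0 in cKO (median 0.25).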

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

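The tests of carried-over tissue, of the allele effects and of a missing ventral cord were chosen after the results they concern had been seen, and those of shared Olig sequence, of the cKO label and of scaling were chosen before. In the counts of single Ctnnb1 transcripts, which the gene-level comparisons do not use, the dE3 library assigned 71.0% of Ctnnb1 counts to ENSMUST00000154687, a transcript with a retained intron, where the WT library assigned 40.9%. The dE3 library also assigned 473 counts to ENSMUST00000178812 of Ctnnb1, where the WT library had 0. Both were picked out because they lie above the control library in data outside the main measurement. In cKO the share of ENSMUST00000154687 was 13.8% (1922 counts, against 7116 in WT). ENSMUST00000007130, whose annotation holds exons 2 to 6, took 65.9% in cKO (9189 counts) and 33.9% in WT (5892 counts). Between dE3 and WT, 34.6% of Ctnnb1 counts moved between transcripts, at percentile 94.4 of 1027 abundant genes (median 2.41%), and between dE3 and cKO 62.0%, at percentile 98.2.

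Muscle and cartilage genes were higher in both mutant libraries, with 27 of 27 measured members at least 2-fold higher in dE3 and 22 of 27 in cKO. Tissue beside the cord carried into the dissection would bring these genes in a fixed proportion. The log2 ratio of the cKO excess to the dE3 excess had an SD of 0.406 over 13 of 14 muscle members. The last, Ckm (0 counts in WT, 28 in dE3 and 0 in cKO), had no excess in cKO and so no such log2 ratio, which leaves carry-over open. Mybpc1, a muscle gene in neither list, had a cKO excess of only 0.00182 of its dE3 excess. An effect of the Ctnnb1 alleles on those tissues or on cell identity stays open too, since the muscle median of 1.99 in cKO comes from 1 library. Of the 14 Wnt targets higher in dE3, 11 had an excess ratio below the central 90% of the muscle and cartilage genes (0.0774 to 0.416). These 11 also lay below every member but Ckm, whose ratio is 0. That argues, for these 11, only against tissue carried into both libraries in the proportion of those lists. Of all 1178 genes higher in dE3, 425 lay below the range. Mybpc1 did so too (1.97 CPM in WT, 499 in dE3 and 2.88 in cKO), and the source of its RNA was not tested. Carry-over in another proportion was not tested either, so it stays open.

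Olig1 and Olig2 were nearly absent from the dE3 library. A dissection without the ventral cord would lower ventral markers together, but the median log2 ratio of 14 floor plate, p3 and motor neuron markers was -0.44 (range -0.84 to 1.21). Loss of reads to genes of like sequence is argued against by the words shared, at most 2.70% for these 2 genes. An effect of the dE3 allele, at a log2 ratio of -9.19 for Olig1, stays open as a hypothesis, because a second dE3 library was not analysed here.

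As a list, Wnt targets were not lower in cKO than in WT. The list median stayed at 0.26 or above under total-count, median-of-ratios and upper-quartile scaling, but these moved the log2 ratio by at most 0.00858 and so could not turn it, and scaling stays open. Ctnnb1 transcript shares could not decide whether the library labelled cKO lacks the deletion. Their shift lay at percentile 92.7 of 1027 abundant genes, between the bounds set for either answer. It also has no direction, so no percentile of it could show which exons were lost. Counts of ENSMUST00000007130, whose annotation holds exons 2 to 6, were higher in cKO (9189 counts) than in WT (5892 counts). Reads per exon were not analysed, so the question stays open. Carried-over tissue that adds target transcripts and covers a fall also stays open, with 11 of 13 cartilage genes higher in cKO and no profile of that tissue alone.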

How the results depend on the processing

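The alternatives were chosen before the data were examined, except the one without genes of shared sequence, which was chosen after. No paired analysis was possible because each genotype has 1 library, and for the same reason no library could be left out in turn. Under total-count, median-of-ratios and upper-quartile scaling, every count of genes stayed within 1.5 times its value and every list median stayed within its counting error (the 95% range over counts redrawn at random). These scaling factors lay between 0.993 and 1.01, so they had little to move. Summing transcript counts changed nothing, by construction, since the gene counts are those sums. Over all alternatives 65 of 96 gene counts, 1314 of 1419 list medians, 126 of 129 list percentiles and 3410 of 3600 named gene ratios moved by less than their tolerance.

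With no filter on low counts, the genes lower were 1151 (dE3 against WT), 1124 (cKO against WT) and 1244 (dE3 against cKO), and those lower in both mutants 335. With at least 100 counts, the genes higher and lower were 636 and 246 (dE3 against WT), 257 and 144 (cKO against WT) and 555 and 357 (dE3 against cKO), with 142 higher in both, 27 lower in both, 16 higher in dE3 and lower in cKO, and 4 the reverse. A threshold of 1.5-fold gave 2052 and 1447, 1302 and 1206, and 2259 and 1722 genes in the same order, and 4-fold gave 405 and 205, 168 and 147, and 343 and 214. These follow from the number of genes admitted. The TPM values gave 380 genes lower in dE3 than in WT, 390 higher and 282 lower in cKO than in WT, and 510 lower in dE3 than in cKO. They gave Ctnnb1 log2 ratios of -0.0262 (dE3 against WT), -0.52 (cKO against WT) and 0.49 (dE3 against cKO), and a Wnt target median of 0.36 for cKO against WT. The cause was not tested. Without genes of shared sequence, 5 genes were lower in dE3 and higher in cKO, against 13.

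The mean of members in place of the median gave 2.41 (dE3 against WT) and 2.11 (dE3 against cKO) for the Wnt targets, and turned the direction of 3 lists that stood apart. Medians of some lists that did not stand apart changed sign too. The 3 were the sex genes in cKO against WT (0.49 against -0.47, carried by Tsix), and in dE3 against cKO the Wnt ligands (0.0457 against -0.34) and neural progenitors (-0.0798 against 0.25). The mean moved 53 further list values past their counting error. In dE3 against WT it gave -1.24 for ventral and intermediate progenitors (median -0.24) and -1.12 for oligodendrocyte lineage genes (median -0.24). For dorsal patterning genes it gave 0.48 (median 0.89). A few extreme members weigh on a mean. Depth limits genes near the floor, where 1 count is a large part of the value.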

Other observations

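The test in the last paragraph was chosen after the values were seen. Both X-inactivation and Y-linked transcripts were present in all 3 libraries. Xist, which silences an X chromosome in female cells, stood at 946 CPM in WT, 1492 in dE3 and 917 in cKO, and the Y-linked Ddx3y at 24.8, 22 and 19.7. Kdm5d, also Y-linked, stood at 41.8, 31.9 and 27.4 CPM. The sex gene list had a median log2 ratio of -0.26 (percentile 3.79) in dE3 and -0.47 (percentile 0.03) in cKO against WT. Tsix, antisense to Xist, had 5, 124 and 238 counts and shared 34.8% of its words with Xist.

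Immediate early genes had a median log2 ratio of 0.50 in cKO (percentile 99.99) and 0.25 in dE3 (percentile 94.6), with the activity-induced gene Fos at 1.56 CPM in WT, 1.28 in dE3 and 2.70 in cKO. Integrated stress response genes had medians of 0.21 in cKO (percentile 98.5) and 0.08 in dE3 (percentile 77.1), with no member past 2-fold in either. Genes of p53 and apoptosis had medians of -0.07 in cKO (percentile 19.2) and 0.02 in dE3 (percentile 56.8). In dE3, 2 of the 14 were higher, Cdkn1a and Perp, the latter also an epidermis marker (2.69 CPM in WT, 6.79 in dE3). Housekeeping genes had medians of 0.17 in cKO (percentile 99.7) and 0.06 in dE3 (percentile 89.1), none past 2-fold. Hoxc13, Hoxd12 and Hoxd13, genes of the tail end of the axis, were the 3 caudal Hox genes higher in dE3, with Hoxc13 at 11.1 CPM against 4.69 in WT.

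The mitochondrial gene mt-Atp6 had 58541 counts in WT, 7742 in dE3 and 6819 in cKO. All of its words occur in another gene, Gm10925, which had 65557, 61715 and 49135 counts. With strand and quantifier unstated, these values are given without a direction.

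The Ctnnb1 total in cKO may reflect loss of the reads of exons 2 to 6 from otherwise unchanged RNA in every cell. That hypothesis gives a ratio to WT of 0.728, and the observed ratio of 0.776 differed from it by 0.0471. The difference was within the bound of 0.1 set for it, but 1 library per genotype leaves no spread for the ratio, and a lower level from all exons would give the same total. In dE3 the same arithmetic gives 0.937, against 0.847 observed. That difference of -0.0898 also lay within the bound, so the bound does not decide the question. The exon shares were taken from ENSMUST00000007130 alone, which held 33.9% of Ctnnb1 counts in WT and 65.9% in cKO. Its estimated counts were 5892 in WT and 9189 in cKO, so the estimates show no loss of this transcript, which holds exons 2 to 6.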
